A study of Homo sapiens with 2 samples.

How the data were processed

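Human Jurkat cells, a T lymphocyte line from an acute T cell leukemia, were profiled for microRNAs (miRNAs) on 1 array. Per the labels, 1 sample was untreated and carried the Hy3 dye, and 1 sample had been given antibodies against CD3 at 10 µg/mL and CD28 at 5 µg/mL for 24 h and carried the Hy5 dye. The labels describe total RNA isolated with TRIzol, mixed with a spike-in miRNA kit and labelled enzymatically. The scanner outputs given for the 2 samples were identical byte for byte, each holding both wavelengths of 1 scan, so they were treated as a single two-colour hybridization. The untreated sample was read from the 532 nm channel and the treated sample from the 635 nm channel. Each group therefore has 1 sample, there is no dye swap, and dye and treatment cannot be told apart.

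Per the file headers, the array carried Exiqon LNA capture probes laid out for miRBase release 8.1, and was read on a GenePix 4000B scanner with GenePix Pro 3.0.6.53, which wrote results format 1.4. Per the file headers, the deposited spot values are intensity, the brightness of each spot's pixels on a linear scale with a local background beside it, with no subtraction or normalization. The percent of saturated pixels per spot is also deposited, and 1 spot in each channel had any. No genome build is named, so no coordinates are given. The authors also deposited a value table with 5223 rows numbered without probe names. Of these rows, 5222 matched a pair of scanner values within a tolerance of 0.001 when the untreated column was taken as the foreground mean minus the local background at 532 nm, and the treated column as the same at 635 nm divided by 1.33. The column medians of this deposited intensity table were 2509 (untreated) and 2168 (treated), and its median log2 treated over untreated was -0.22. Scale and direction were settled by this match, with no centring, while the rule that left out the other spots stays unknown. The table served as an alternative, recomputed on its scale from the scanner values. This recomputation is not the table itself. It left out blocks 17, 18 and 19, of which the table holds 325 spots, and it took in spots that the table leaves out.

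The array had 6720 spots in 32 blocks. The layout repeats every 8 blocks, which gives 4 spot sets and 4 spots per probe. The scanner software marked 0 spots as bad. In blocks 17, 18 and 19 the Hy3 marker spots were no brighter than 2 times the empty spots, so the 630 spots of these blocks were left out. The plan had spoken of usable spots without defining them, and this definition was made after the data were seen. Foreground and background medians were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. The dyes were then normalized by loess within the array, with empty, marker, spike-in and negative control spots at weight 0. The log2 ratio of a probe, treated over untreated, is the mean over its usable spots. Its SD over those spots is called the spot SD, and it measures spread within 1 array only. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

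A spot counted as detected where its foreground median exceeded its local background median by 2 background SD. A probe counted as detected where at least 50% of its usable spots were. A miRNA counted as higher or lower where it was detected in both channels, differed at least 2-fold (a log2 ratio of at least 1 in size) and had every usable spot on the same side of 0. For the 4 miRNAs with 2 probes, the mean over probes detected in both channels was taken. With 1 sample per group there is no test across samples and no p-value. Depth on an array is signal over background, and a single array limits the precision.

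Before the data were examined, 15 miRNA lists, 9 lists of markers of other cell types, the size rule and the alternatives were fixed. The lists were T cell activation (reported higher and reported lower), let-7, miR-17~92 with paralogues, miR-181, miR-15/16, miR-23/27/24, miR-29, miR-30, haematopoietic miRNAs, miR-34 with p53-linked miRNAs, the 14q32 cluster, the 19q13 cluster, star strands and viral miRNAs. No probe bears a viral prefix, so the viral list has no value. The fixed lists use newer names, and a table of older names was written once the array's names were known, from the names alone. For a list with at least 3 members detected in both channels, its median log2 ratio was placed among 10000 random lists of the same size, matched on brightness in 5 bins, as a description of these 2 samples.

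The rule for the miRNAs named in the text has several parts. It takes the 12 highest and the 12 lowest among those that meet the 2-fold rule. It takes up to 3 members of each list with the largest log2 ratios in size among those detected in both channels. It always takes miR-155, miR-146a, miR-21, miR-150, miR-181a, miR-17, miR-92a, miR-182, miR-214, miR-221, miR-222 and let-7a. It takes up to 3 miRNAs per side detected in 1 channel only, by the largest lower bound of the ratio, and the 5 brightest. Any other miRNA or probe named here was chosen after its values were seen.

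A miRNA detected in 1 channel only was ranked by the brighter channel's log2 value minus the higher of the dimmer channel's own value and the lowest value among detected probes, per channel after loess. For each of those named except miR-202*, the miRNA's own value in the other channel was the higher, so the difference equals the measured log2 ratio in size. It is given as that ratio, not as a bound, and is open to dye bias.

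The calling rule was tested on simulated data with the 1469 probes of the array's layout, 200 of them changed. All 89 of 89 detected probes made 3-fold different and 84 of 84 made 4-fold different were recovered, and 0 of 867 detected probes left alone were called. The changed probes were drawn from bright probes only, and changed probes that were not detected are outside these counts. Spot residuals were taken about each probe's own mean and shuffled over probes, which drops any link of noise to brightness. Recovery of changes near 2-fold or in dim probes was therefore not tested. Each change was applied to a probe's whole signal above background. Signal that does not come from the probe's own miRNA would shrink a change, and recovery in its presence was not tested. The list percentile was tested on 308 simulated miRNAs, where 7 of 100 random lists of 8 fell outside the central 95% and a list shifted by a log2 ratio of 0.3 reached percentile 100.

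Alternatives planned before the data were examined covered background correction, dye normalization (including scaling on the spike-ins and none), the mean of pixels, the detection limit, the summary over spots, leaving out each spot set, the deposited table's scale, the size limit and the same-side rule. Keeping every block, loess within each block, and detection against the empty spots by 3 of their SD were added after the data were seen.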

Results

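The study asked which miRNAs differ between Jurkat cells at rest and Jurkat cells stimulated through CD3 and CD28, the T cell receptor complex and its main costimulatory receptor. Jurkat is a human leukemic T cell line widely used for T cell receptor signalling. One untreated sample and 1 sample kept with both antibodies for 24 h were labelled with different dyes and hybridized together to 1 array of locked nucleic acid probes. The array held 452 probes for 448 human miRNAs. There are no replicate samples, so each ratio below describes these 2 samples, and every SD is a spot SD within the array. Dye and treatment cannot be told apart, since the dyes were not swapped.

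Median signal stood well above median background in both channels. The median spot foreground was 2123 (untreated) and 2434 (treated), against median local backgrounds of 64 and 59. Of 303 empty positions, 1 was detected in the untreated channel and 0 in the treated channel. The 3 blocks without a Hy3 marker signal, seen in the plot of marker spots by block, were left out, which leaves 6090 spots.

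**Figure D1:**
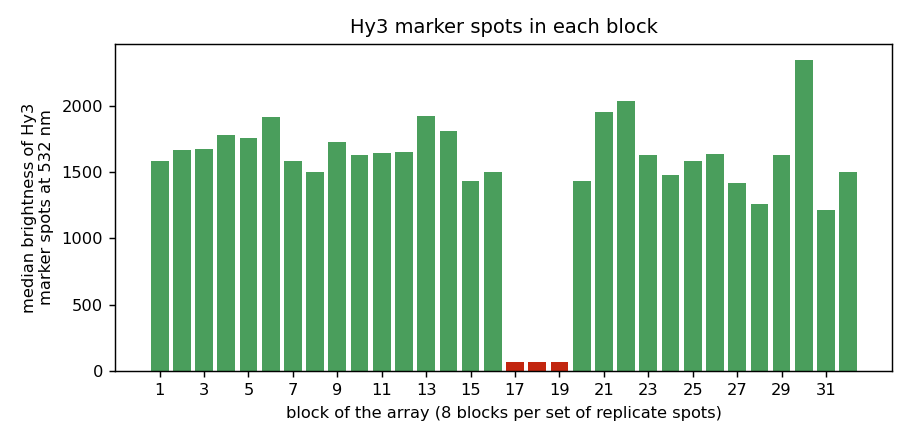
Median brightness at the Hy3 wavelength (linear scanner units) of the Hy3 marker spots in each of the 32 blocks of the array. Blocks 17, 18 and 19 (red) read at the level of empty spots and were left out, and the other blocks (green) were kept.

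Of the 448 human miRNAs, 334 (74.6%) were detected in untreated cells and 329 (73.4%) in treated cells. By the same rule 76.2% (untreated) and 77.7% (treated) of the probes with no known human target were detected. A detected probe, or a bright one, therefore does not by itself show that its miRNA was present. Both channels detected 308 of them, 26 were detected in untreated cells only, 21 in treated cells only, and 93 in neither. Detection in 1 channel only depends on that channel's local background SD and does not show absence from the other sample. For example, miR-200b counted in untreated cells only, with signals of 3657 (untreated) and 3934 (treated). Likewise, miR-30d counted in treated cells only, with 2079 (untreated) and 3249 (treated). The 5 brightest human miRNAs were miR-363*, miR-617, miR-639, miR-622 and miR-361. Of these, miR-361 had a log2 ratio of 0.31 (spot SD 0.12), above 0 in 4 of 4 spots, while miR-363* stood at 0.03 (spot SD 0.07) and miR-622 at -0.05 (spot SD 0.10).

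No human miRNA detected in both channels passed the 2-fold rule between CD3/CD28-treated and untreated cells. Of the 308 miRNAs detected in both channels, 0 were at least 2-fold higher and 0 at least 2-fold lower in treated cells. Closest were miR-487b, a member of the 14q32 cluster, with a log2 ratio of 0.96 (1.94-fold, spot SD 0.60, 4 spots), and miR-450 with 0.72 (1.64-fold, spot SD 0.57, 3 spots). At the low end stood miR-501 with -0.63 (0.644-fold, spot SD 0.48, 3 spots). These 3 are all that passed 1.5-fold with every spot on the same side, and miR-450 and miR-501 were chosen after their values were seen. The other probe for miR-450 was not detected in both channels, and its log2 ratio was 0.01 (spot SD 0.44, 4 spots).

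The values of miR-487b, miR-450 and miR-501 depended on the pixel statistic. With the mean of pixels in place of the median, miR-487b stood at 0.33, miR-450 at 0.18 and miR-501 at -0.09, and plain background subtraction put miR-487b past 2-fold at 1.15.

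Most miRNAs lay close to a ratio of 1. The median log2 ratio was -0.00055 and the SD over miRNAs 0.145, with the central 95% between -0.24 and 0.31 (0.849-fold to 1.24-fold). The log2 ratios of 275 of the 308 miRNAs (89.3%) were within 0.2 of 0. The median spot SD of a miRNA was 0.121. All usable spots lay above 0 for 33 miRNAs and below 0 for 33, 66 in all, where a fair coin for each spot would give 50.8. The ratios are relative to the bulk of the probes, and scaling on the spike-ins moved the median of all detected miRNAs by 0.42, no dye normalization by 0.21 and the deposited table's scale by -0.19.

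**Figure D2:**
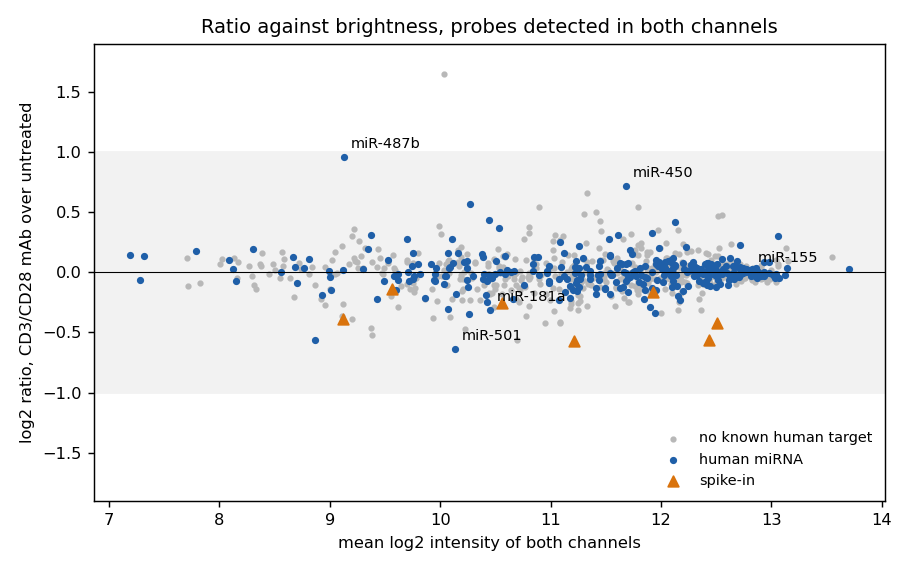
Log2 ratio of treated over untreated against mean log2 intensity for probes detected in both channels, with human miRNAs in blue, probes with no known human target in grey and spike-ins as orange triangles. The grey band marks log2 ratios from -1 to 1. All human miRNAs lie inside it, with miR-487b at 0.96 and miR-501 at -0.63, and 1 grey probe lies above it at 1.65.

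The miRNAs that earlier work reports as higher in activated T cells showed no common shift. Of the 14 on the array, 10 were detected in both channels, with a median log2 ratio of 0.0024, at percentile 51.7 of random lists matched on brightness. Both miR-155, made from a transcript induced in activated lymphocytes, at 0.02 (spot SD 0.09, 4 spots), and miR-146a, a feedback regulator of NF-κB signalling, at 0.01 (spot SD 0.10, 4 spots), had ratios smaller than their spot SD. The ratio of miR-221 was 0.28 (spot SD 0.48), that of miR-182, which interleukin-2 signalling induces in helper T cells, was -0.23 (spot SD 0.35), and that of miR-214 was 0.07 (spot SD 0.08). Relative to all detected miRNAs, miR-221 ran from 0.04 to 0.56 over the alternatives and miR-182 from -0.33 to -0.03. In miR-212 all 3 spots were below 0, with a mean of -0.20 (spot SD 0.17). Neither miR-21 nor miR-222 passed the local background limit in either channel, although miR-222 had signals above background of 795 and 524, with a log2 ratio of -0.40 (spot SD 0.75).

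Among miRNAs reported as lower in activated T cells, miR-181a had the lowest ratio. Its log2 ratio was -0.31 (0.804-fold, spot SD 0.22), below 0 in all 3 usable spots, and it stayed below the median of all detected miRNAs under each alternative, by -0.44 to -0.15. The usable spots ran from -0.56 to -0.15, and the mean signals before dye normalization were 2057 (untreated) and 2049 (treated). With every block kept, the mean for miR-181a was -0.22 and its highest spot was at 0.05. This miRNA tunes the sensitivity of the T cell receptor and is abundant in thymocytes. For miR-150, a miRNA of resting mature lymphocytes, the ratio was 0.13 (spot SD 0.25), and for miR-181b 0.10 (spot SD 0.05). Of the 10 members on the array 7 were detected in both channels, with a median of 0.02 at percentile 69.4. The miR-181 family as a whole had a median of -0.02 over 3 members (percentile 44.2), with miR-181d at -0.02 (spot SD 0.18).

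The growth-linked miR-17~92 cluster and its paralogues had a median log2 ratio of 0.05 over 10 detected members, at percentile 93.4. The probe shared by miR-17-5p and miR-106a had the highest ratio of the group, 0.42 (1.34-fold, spot SD 0.37), above 0 in all 3 spots. It was 0.19 with the mean of pixels, 0.23 without spot set 1 and 0.28 with loess within each block. Next came miR-92 (now miR-92a) at 0.22 (spot SD 0.36), or 0.03 with the mean of pixels, and miR-17-3p at 0.15 (spot SD 0.27), the latter at -0.14 relative to all detected miRNAs on the deposited table's scale. The 2 probes for miR-20a disagreed, with 0.33 and -0.05.

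The let-7 family, which restrains proliferation in many tissues, had a median of 0.01 over 7 members (percentile 60.9). Within it let-7a was at -0.02 (spot SD 0.04), let-7b at 0.09 (spot SD 0.06), let-7i at -0.07 (spot SD 0.11) and miR-98 at -0.06 (spot SD 0.23). The miR-15/16 family had a median of -0.01 over 6 members (percentile 34.7), with miR-15b at -0.14 (spot SD 0.09) and below 0 in all 3 spots, miR-15a at -0.10 (spot SD 0.17) and miR-424 at 0.04 (spot SD 0.21). Under loess within each block miR-15b lay 0.01 above the median of all detected miRNAs.

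In the miR-29 family the median was -0.08 over 3 members (percentile 13.1), from miR-29c at -0.09 to miR-29b at -0.02, with miR-29a at -0.08. The miR-23/27/24 clusters had a median of -0.05 over 4 members (percentile 21.1), with miR-24 at -0.22 (spot SD 0.43), miR-23a at -0.12 (spot SD 0.30) and miR-23b at 0.07 (spot SD 0.24). Each of these changed sign over the alternatives. Relative to all detected miRNAs, miR-24 ran from -0.37 to 0.04, miR-23a from -0.20 to 0.02 and miR-23b from -0.07 to 0.13. The miR-30 family had a median of -0.0060 over 6 members (percentile 43.6), although miR-30a-5p was at -0.35 (spot SD 0.45), with miR-30b at 0.10 (spot SD 0.19) and miR-30c at -0.07 (spot SD 0.27). On the same relative footing, miR-30a-5p ran from -0.55 to -0.10, miR-30b from -0.02 to 0.15 and miR-30c from -0.31 to 0.07. Without loess the miR-30 median lay at -0.22 relative to all detected miRNAs.

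Haematopoietic miRNAs had a median of 0.02 over 7 members (percentile 70.4). Among them miR-142-3p, a miRNA of blood cells, was at 0.13 (spot SD 0.05), above 0 in 4 of 4 spots. In the group of miR-34 and p53-linked miRNAs the median was -0.0079 over 5 members (percentile 50.2). Here miR-194 was at 0.23 (spot SD 0.13), above 0 in 4 of 4 spots, miR-34a at -0.13 (spot SD 0.57) and miR-34c at -0.06 (spot SD 0.27). Star strands had a median of 0.0026 over 17 members (percentile 51.2), with miR-302b* at 0.19 (spot SD 0.32), miR-517* at -0.18 (spot SD 0.12) and miR-182* at 0.16 (spot SD 0.21). Over the alternatives, relative to all detected miRNAs, miR-302b* ran from 0.03 to 0.26, miR-517* from -0.24 to -0.02 and miR-182* from -0.03 to 0.31.

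The miRNAs of the imprinted 14q32 cluster lay slightly above the rest. Their median log2 ratio was 0.06 over 27 detected members, at percentile 99.9 of random lists, whose medians had a central 95% from -0.03 to 0.04. Besides miR-487b, the largest values were miR-323 at 0.32 (spot SD 0.52), or 0.17 with the mean of pixels, and miR-380-5p at 0.16 (spot SD 0.28), and 0 members reached 2-fold. The percentile was 84.0 with the mean of pixels, and of 18 lists with a percentile 0.9 would lie outside the central 95% by chance.

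The primate-specific 19q13 cluster had a median of 0.04 over 35 detected members (percentile 98.6), with miR-517a-517b at 0.28 (spot SD 0.27), above 0 in 4 of 4 spots and 0.11 with the mean of pixels, miR-517c at 0.20 (spot SD 0.28) and miR-519a at -0.22 (spot SD 0.24). Its rule by number also takes in miR-513 and miR-514, which lie elsewhere in the genome. Without them, a choice made after the data were seen, the median over 33 members was 0.03 at percentile 94.9. With them, the percentile stayed above the central 95% in 5 of 15 alternatives, with the 4 settings without loess counted once, and was as low as 90.6.

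**Figure D3:**
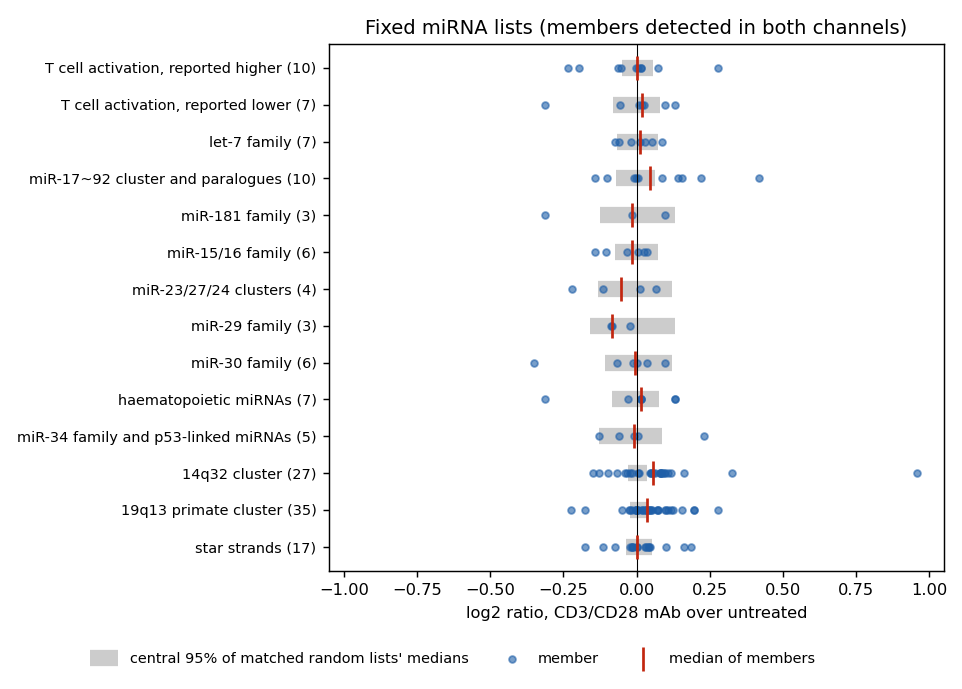
Log2 ratio of treated over untreated for the members of each fixed list detected in both channels (blue points, number in brackets), with their median (red mark) and the central 95% of medians of random lists matched on brightness (grey bar). The medians of the 14q32 and 19q13 clusters lie right of their grey bars, at 0.06 and 0.04, which for 19q13 held in 5 of 15 distinct alternatives, and all other medians lie inside theirs.

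Among miRNAs detected in 1 channel only, ranked by the lower bound of the ratio, miR-632 came first of those detected in untreated cells, with a log2 ratio of -0.91 (spot SD 0.05), with its 3 usable spots between -0.96 and -0.87. Next by the bound were miR-126* at -0.69 (spot SD 0.56) and miR-488 at -0.61 (spot SD 0.76), the latter with 1 of 3 spots above 0. The ratio of miR-202* was -0.75 (spot SD 0.43), but its treated signal lay below the lowest detected probe, which leaves at least 1.08-fold. Of those detected in treated cells, miR-504 was at 0.81 (spot SD 0.53), miR-127 at 0.77 (spot SD 0.78), with a spot at -0.12, and miR-197 at 0.69 (spot SD 0.46). Apart from miR-202*, for which it was not tabulated, all were closer to 0 with the mean of pixels, with miR-632 at -0.17, miR-126* at -0.39, miR-488 at -0.22, miR-504 at 0.19, miR-127 at 0.21 and miR-197 at 0.35. Without spot set 1 miR-488 was at -0.17, and on the deposited table's scale miR-504 and miR-127 lay 0.18 and 0.19 above the median of all detected miRNAs.

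Markers of cell types other than T cells were read as well. Leaving out miR-223, miR-214 and miR-9, which also stand in the T cell or haematopoietic lists, 18 of 35 such miRNAs on the array were detected in both channels, with log2 ratios from -0.19 to 0.07. Several were among the brightest human probes, with miR-203 (an epidermal miRNA) at brightness percentile 98.2, miR-122a (liver) at 96.4 and miR-124a (neurons) at 92.4. Others were near the floor, with miR-128b at 3.57 and miR-200a at 4.69. With these 3 counted in, 3 of the epithelial markers were detected in both channels, of the muscle markers 4, of the stromal markers 4, of the pluripotent markers 3 and of the neural markers 2. Only miR-486 of the erythroid markers was, and the single myeloid, endothelial and liver markers (miR-223, miR-126 and miR-122a) all were. The list medians were -0.06 (epithelial), -0.06 (muscle), 0.05 (stromal) and 0.01 (pluripotent), at percentiles 10.3, 5.85, 84.1 and 46.5.

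Probes for no known human target gave as much signal as probes for human miRNAs. Of 853 such probes 616 (72.2%) were detected in both channels, against 310 of 452 human miRNA probes (68.6%). Their median signal above background in untreated cells was 2186, against 1936 for human miRNA probes and 608 for the negative control probes, of which 5 of 8 were detected in both channels. The SD of their log2 ratios was 0.157, against 0.146 for human miRNA probes and 0.286 for the negative controls detected in both channels. Of these, negative control 5 was at 0.52 (spot SD 0.50) and negative control 7 at 0.38 (spot SD 0.18), above 0 in all 3 spots, both larger in size than the ratio of miR-181a.

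**Figure D4:**
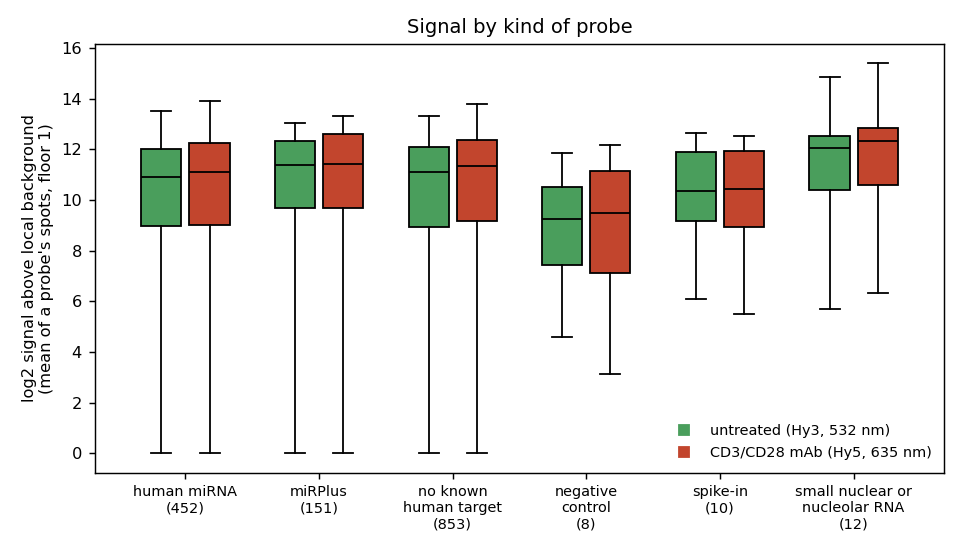
Log2 signal above local background per probe for each kind of probe (number of probes in brackets), untreated in green and treated in red. Boxes span the quartiles with the median as a line, and whiskers reach the lowest and highest probe, with values below 1 drawn at 1. Human miRNA probes and probes with no known human target have medians of 1936 and 2186 in untreated cells on the linear scale.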

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

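The tests in this part were chosen after the result they bear on was seen. Probe 13241, which the array lists with no known human target, was 1 probe outside the human miRNAs, and the only one among the noncoding, miRPlus, negative control and no-target probes, that passed the 2-fold rule. It stands out as a signal in probes the comparison does not use. Its log2 ratio was 1.65 (spot SD 0.38), higher in treated cells in 4 of 4 spots, which ran from 1.16 to 1.97. Across 12 alternatives its ratio stayed between 1.15 and 1.96, but without spot set 1 and without spot set 2 it was not detected in both channels and so did not pass the rule. Its target was not worked out here.

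Probes for no human miRNA were as bright as human miRNA probes (72.2% against 68.6% detected in both channels). In the kept blocks, only 0.330% of the empty positions were detected in the untreated channel, which argues against a layout shifted onto them. The Hy3 marker had 1577 (untreated) and 3.87 (treated) over 145 usable spots. Blocks were kept by the brightness of this marker, so it cannot bear on the layout. The Hy5 marker, which played no part in keeping blocks, went against the empty positions. It had 744 (untreated) and 698 (treated) over 3 usable spots and was detected in the untreated channel only. Probe names exchanged among filled positions would leave empty positions dark, so the empty positions cannot decide on such an exchange. Binding that does not depend on a probe's target would place miRNAs restricted to other cell types (the 35 outside the T cell and haematopoietic lists) near the middle of the brightness range. Of these, 10 lay above the 80th percentile and 14 below the 20th, so their median of 25.9 describes few of them and cannot decide. This explanation stays open. No biological explanation was tested.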

How the results depend on the processing

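The counts of 0 higher and 0 lower miRNAs held under most alternatives. The higher count was 1 with plain background subtraction, 1 with no background correction and 1 without spot set 4 (miR-487b each time), 1 without spot set 2 (miR-450), 2 with spike-in scaling (both) and 2 at a 1.5-fold limit. The lower count was 1 on the deposited table's scale (miR-421 at -1.07) and 1 at 1.5-fold (miR-501). With detection at 1 background SD, 377 human probes were detected in untreated and 369 in treated cells, at 3 background SD 303 and 305, and against the empty spots 407 and 427, beside 336 and 331. The 93 miRNAs detected in neither channel failed the limit on the local background SD. Some of them had no signal to lose, such as miR-511 with -0.5 (untreated) and -7.75 (treated) above background. Against the empty spots, 403 miRNAs were detected in both channels. Spike-in scaling moved the median of all detected miRNAs by 0.42, no dye normalization by 0.21 and the deposited scale by -0.19, so list medians are compared relative to that median, a choice made after the data were seen. On this footing the 4 settings without loess give the same values and count once, and 6 of 210 list values moved by more than their SD between spot sets. Without loess (global median centring, median centring over detected probes, spike-in scaling, no dye normalization) the medians were 0.043 for T cell activation, reported higher, 0.064 for T cell activation, reported lower, and -0.22 for the miR-30 family. The 14q32 cluster was at 0.025 with the mean of pixels and 0.024 with loess within each block, and the miR-29 family at -0.022 without spot set 4. Of 840 values of named miRNAs 107 moved by more than their spot SD, not taken relative to that median. Of these, 38 came with spike-in scaling, 29 on the deposited scale and 22 with no dye normalization, the 3 settings that moved the median of all detected miRNAs most. The 14q32 percentile stayed above the central 95% in 11 of 15 such distinct alternatives (84.0 to 100) and that of 19q13 in 5 of 15 (90.6 to 99.6). The cause of these moves was not tested. Keeping marked spots was not run, because the scanner software marked 0 spots. No paired analysis was possible because each group has 1 sample.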

Other observations

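The tests of misregistered wavelengths and of the slide position of the spike-ins were written before their results were seen, and the other tests in this part after. Small nuclear and nucleolar RNAs, which guide splicing and RNA modification, were strongly detected, with 10 of 12 probes detected in both channels. The 2 probes for U6, a spliceosomal RNA often used to scale miRNA assays, were both higher in treated cells, at 0.68 (spot SD 0.26) and 0.25 (spot SD 0.17), with ranges over the 12 alternatives run for these probes of 0.58 to 1.10 and 0.16 to 0.70. The brightest, SNORD3@, was at 0.02 (spot SD 0.04), SNORD13 at -0.12 (spot SD 0.07) and SNORD12 at -0.26 (spot SD 0.48). Of the miRPlus probes, the supplier's own set, 111 of 151 were detected in both channels, and their ratios had a median of -0.02 and an SD of 0.106.

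The spread of ratios among human miRNAs was as wide as among probes for no human miRNA, with a ratio of SDs of 0.930, which fits a spread that both kinds of probe share. A change in miRNA level that every spot set carries would make the 4 spot sets correlate. Across 310 human probes, which are not independent replicates, the mean correlation between spot sets was 0.0222 (pairs from -0.258 to 0.254, bootstrap interval -0.0933 to 0.155). Such a change is therefore not shown across the probes as a whole. Probes with no known human target had 0.0680 (bootstrap interval -0.0745 to 0.244), although probe 13241 among them was higher in 4 of 4 spots. The correlation can thus miss a large change in a few probes, and neither that nor a small change is excluded. Wavelengths read from slightly different positions may add to the spread, since a spot's distance from its probe's median grew weakly with its relative background SD (rho 0.120), between the values set for and against that explanation. The effect of the treatment on the spread and that of the dyes cannot be told apart with 1 array.

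The spike-ins had lower ratios than the other probes, from -0.05 to -0.57, or from -0.14 to -0.57 among the 7 detected in both channels. Where they lie on the slide is argued against, because the 4 bright ones were below the other probes of their block in 100% of the 29 usable blocks (median difference -0.42). A dye effect that depends on brightness is argued against too, because after loess on brightness their median was still -0.49. More small RNA per microgram of total RNA in the treated cells may account for a shift common to all spike-ins. Unequal amounts of added spike-in may do so too. With 1 labelling per sample these cannot be told apart. A common shift would not give the differences between spike-ins, such as -0.14 (spot SD 0.12) for spike-in c and -0.57 (spot SD 0.10) for spike-in i. The cause of those differences was not tested.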
